A study of Bos taurus with 8 samples.

How the data were processed

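Granulosa cells were collected by transvaginal needle aspiration from 4 Holstein heifers at 8, 11 and 14 months of age, after progesterone treatment and ovarian stimulation with FSH, per the labels' protocols. Total RNA was amplified linearly, labelled with Cy3 or Cy5 and hybridised on 8 dual-colour arrays of the bovine EmbryoGENE design. In 4 arrays the RNA of a heifer at 8 months was set against RNA of the same heifer at 14 months, and in the other 4 the RNA at 11 months against that at 14 months. The younger age carried Cy5 in heifers 1 and 2 and Cy3 in heifers 3 and 4, per the labels. The labels name granulosa cells as the source of every sample, and the samples are described as such here. The design text of the series speaks of blastocysts instead, a conflict about the identity of the samples that was not settled and that bears on every value.

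The scanner tables that the authors deposited give, per the file headers, the median and mean pixel intensity of each spot and of its local background in both channels, without background correction or normalization. Another column of these tables marks spots that were left out of the summary lines, between 22 and 59 per array, and these spots were left out here too. The image software is not given in the sources used here. A table of log2 ratios that the authors deposited was set against the scanner intensities. Its columns followed Cy5 over Cy3 of the median intensities after subtraction of the local background and loess, with correlations over probes from 0.999 to 1, slopes from 0.989 to 1.00 and column medians from -0.02 to 0.00083. Scale, centring and direction were found in this way, and the method the authors used to normalize is not given in the sources used here.

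Values were computed with limma 3.58.1 in R 4.3.3. Median intensities were corrected with normexp and an offset of 50, and log2 ratios were normalized by loess within each array, with control spots given no weight and then removed. A probe was called above background where its intensity exceeded the mean of the 153 negative control spots by 2 SD on that array and channel. Of 43794 probes, 22692 were kept because they were above background in at least 3 of 4 heifers at 1 or more ages. A model with a term for 8 against 14 months, a term for 11 against 14 months and a dye term was fitted to all 8 arrays, with the heifer as a random block. The estimated correlation within heifers was 0.159, the residual degrees of freedom were 5 and the prior degrees of freedom 3.72. The contrast of 8 and 11 months is the difference of both terms. Benjamini-Hochberg adjustment was done over the kept probes, and an adjusted p under 0.05 was the threshold. The replicate numbers pair the arrays because the labels name the same animals in both comparisons. Deviations from the group means correlated at 0.379, 0.277, 0.447 and -0.110 between the arrays of heifers 1 to 4.

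Gene symbols came from the platform annotation, which is old. Of all probes, 21790 had 1 symbol, 0 had several and 22004 had none. Symbols of 21549 probes matched the current bovine gene table of the ARS-UCD2.0 assembly, 1524 of them under a newer symbol, and 241 did not match and were kept as given. The brightest kept probe stood for each of 10215 genes, and 2109 genes had 2 or more kept probes. A probe not above background on any array of an age has no reliable level there. Its fold is an estimate from intensities per channel after loess and scaling of brightness between arrays. Values under the lowest of any probe above background were raised to it, and sampling error was left out. Each array gives a heifer's ratio, and the number of arrays limits the precision.

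The choices that follow were made before the data were examined. The genes named are the 10 largest rises and 10 largest falls per comparison among genes past the threshold with the same direction in all 4 heifers. Where fewer than 5 passed, the 5 genes with the smallest p and a change of at least 1.5-fold are given by their values. Members of each gene list with the smallest p are named too, and CYP19A1, FSHR, LHCGR, STAR and VEGFA in every comparison. Any other gene named, such as single members of the added lists, was picked for naming after its values were seen. The 23 gene lists covered granulosa identity and FSH response, LH and ovulatory response, steroidogenesis, cholesterol biosynthesis, cell cycle, angiogenesis, hypoxia and glycolysis, extracellular matrix, apoptosis, the insulin and IGF system, TGF-beta and BMP signalling, stress and immediate early genes, antioxidant defence, ribosomal proteins, mitochondrial respiration, interferon response, and markers of leukocytes, red blood cells, theca, endothelium, stroma, oocytes and epithelium. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, with the estimated correlation and with fry beside it, adjusted over the 23 lists. After the data were seen, 2 lists were added from textbook knowledge, for stratified squamous epithelium and for motile cilia, and their medians were set against 10000 random lists of the same size and brightness. Random lists held genes drawn singly, which leaves out the correlation between markers of a cell type. Counts of random lists as high are therefore not p-values and overstate how rare such a median is.

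The procedure was tested on simulated data. With 100 probes changed by a log2 of 1 between 8 and 14 months among 22692 probes, 29 were called, and with a log2 of 2, 78 of 100 were called, with 5 false calls in all. For 8 against 11 months the same simulation gave 6 and 60 calls with 2 false ones. Alternatives changed the background correction, normalization, filter, dye term, heifer block, arrays in the fit, array weights, probe summary and set test, used the authors' log2 ratios, and left out each heifer in turn. Another 6 were added after the data were seen, among them the medians of both added lists in each array as covariates and fits without the arrays in which cilia genes stood high. Without the 8-month arrays of heifers 1 and 2, only Cy3 carried 8 months, so the dye term came from the 11-month arrays. All 8 arrays were used.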

Results

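Granulosa cells are the somatic cells that line the ovarian follicle and convert androgens to oestradiol under FSH. Their transcripts were compared within 4 heifers between 8 or 11 months and 14 months of age, an interval around puberty, with 4 arrays for each comparison. Median probe intensities lay between 220 and 329 per array and channel, against 163 to 295 for negative control spots. Between 43.3% and 57.3% of probes were above background, and 0 to 21 probes per channel were saturated. The log2 ratios had SDs from 0.43 to 0.98. Every log2 change below is the younger age minus the older, as fitted, with the SD over the 4 heifers, and p-values are adjusted p from limma.

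The comparison of 8 with 14 months asks how cells from younger ovaries differ from those of the same animals at the oldest age sampled. Several keratins were among the largest rises at 8 months. KRT78 rose by 4.34 ± 1.90 (SD, n = 4; adjusted p = 0.0123) and KRT4, a keratin of mucosal linings, by 4.29 ± 1.97 (adjusted p = 0.0167). KRT6A rose by 3.46 ± 2.12 and KRT6C by 3.33 ± 1.78, although signal of these near-identical copies is uncertain. PPL, which encodes the cornified envelope protein periplakin, rose by 3.32 ± 0.63 with the lowest adjusted p, 0.00281, and PI3, an antiprotease of epithelia, by 3.35 ± 1.90.

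Other large rises were in FOXA2, a forkhead transcription factor of glandular epithelium, at 3.93 ± 1.66, and WWC1, a regulator of Hippo signalling, at 3.87 ± 1.52, with 3.14 for its other probe. SLC30A7, a zinc transporter of the Golgi, rose by 3.55 ± 0.34. RPRD2 rose by 3.47 (SE 0.49, adjusted p = 0.0131), about 11.1-fold, by 1 probe that was not above background on any 14-month array. The size of this rise is therefore uncertain, and its other probes gave -0.03 and 0.40. The largest falls were smaller. TAF15, an RNA-binding protein, changed by -1.77 ± 0.53 (adjusted p = 0.0428), the growth factor FGF5 by -1.64 ± 0.51, LOC508153 by -1.63 ± 0.53 and HNRNPK by -1.61 ± 0.24, the last uncertain because of near-identical copies. DCTN5, a dynactin subunit, changed by -1.56 ± 0.42, with -0.38 and -0.26 for its other probes. SRGN, the proteoglycan core protein of secretory granules, changed by -1.55 ± 0.37, LOC512005 by -1.48 ± 0.47, IDH3A by -1.47 ± 0.49, LXN by -1.43 ± 0.73 and RGN by -1.42 ± 0.62. With the squamous and cilia medians as covariates, PI3 stood at 0.94 (adjusted p = 0.526), KRT4 at 2.43, KRT78 at 2.60, FOXA2 at 2.15 and WWC1 at 2.45. FGF5, HNRNPK and IDH3A lay lower in that fit than without it, at -2.22, -2.06 and -1.71, and SRGN and RGN kept most of their change, at -1.22 and -1.15, but with larger SEs these 5 fell short (adjusted p from 0.0517 to 0.0831).

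**Figure D1:**
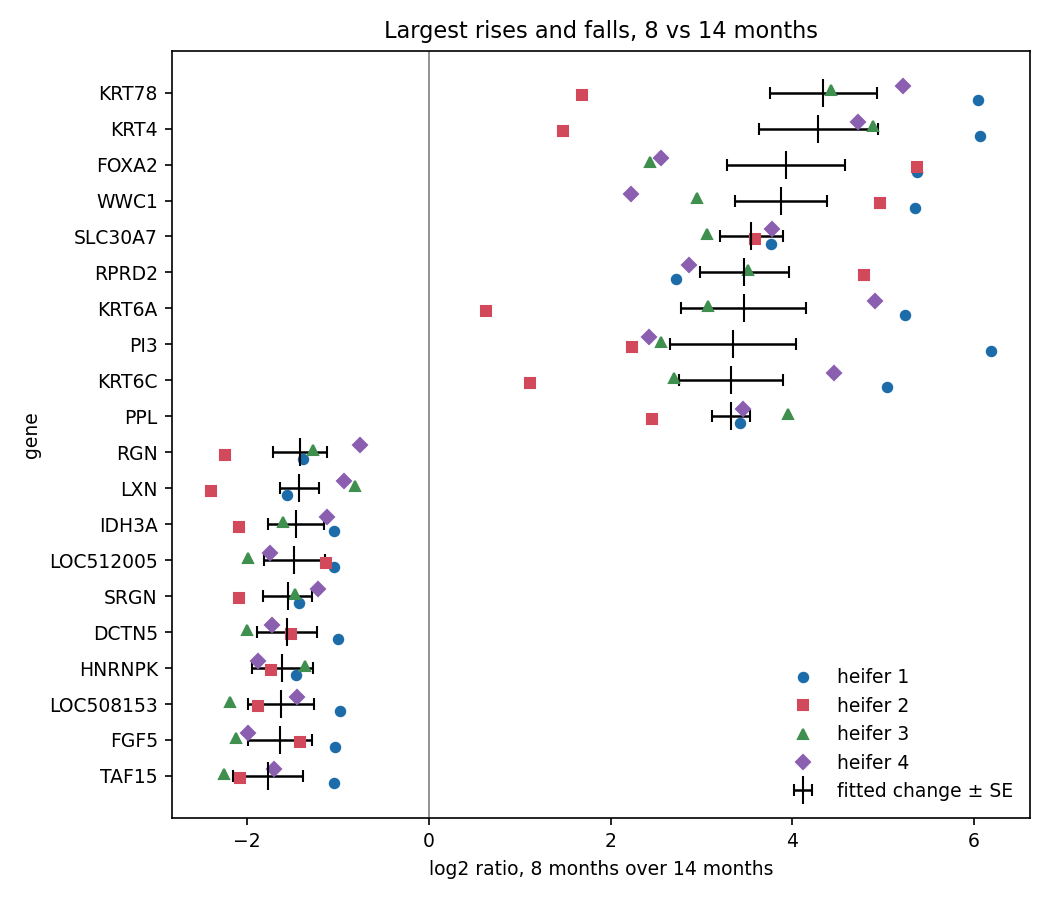
Log2 ratio of 8 over 14 months on the horizontal axis for the 10 largest rises and 10 largest falls, 1 gene per line. Points are the 4 heifers and black bars the fitted change with its SE. All points lie on the same side of 0 for each gene, and heifer 2 has the lowest ratio for KRT78 (1.68), KRT4 (1.47) and KRT6A (0.62).

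In all, limma called 871 of 22692 probes between 8 and 14 months, of which 735 rose and 136 fell. Of these, 552 carried a gene symbol. Judged by the brightest probe of each gene, 474 genes were called, 393 risen and 81 fallen. At an unadjusted p under 0.05 there were 5617 probes. The ratio had the same direction in all 4 heifers for 31.5% of probes, where chance gives 12.5%. The count rests on heifers 3 and 4, since 0 probes were called without heifer 3 and 37 without heifer 4, against 1250 without heifer 1 (662 rose) and 1705 without heifer 2 (988 rose). The share of rises among the calls, 84.4%, was 73.8% of 1708 with median normalization, 60.4% of 2020 with a dye term per comparison, 50.9% of 3553 with array weights, 50.7% of 3236 with only the arrays of this comparison and 33.2% of 1493 with the added squamous and cilia medians as covariates.

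Among the lists, the epithelial markers shifted up at 8 months, with all 12 measured members higher and a median of 1.51 (camera adjusted p = 8.27e-05; adjusted p = 0.899 with an estimated correlation). Of these, 3 rose, the tight junction gene CLDN4 by 3.07 ± 1.91, the mucin MUC1 by 2.75 ± 1.69 and KRT7 by 2.69 ± 0.97, and 7 passed when adjusted over the list alone. With the covariates none of these 3 passed, CLDN4 at 1.36, MUC1 at 1.16 and KRT7 at 0.70. CLDN1 stood at 1.64 ± 0.90 without passing (adjusted p = 0.0595). The cell cycle list shifted down, with 27 of 31 members lower and a median of -0.38 (camera adjusted p = 0.00371, and 0.899 with an estimated correlation). However, 0 of its members passed limma's test, also adjusted over the list alone. An unadjusted p under 0.05 was found for 9 of 31, against 24.75% of all probes. Examples were cyclin B1, CCNB1, at -1.17 ± 0.38 and the kinesin KIF20A at -0.70 ± 0.23. Without the 8-month arrays of heifers 1 and 2, in which motile cilia genes stood highest, neither shift passed, with medians of 0.42 and -0.04, nor did either with the squamous and cilia medians as covariates. In heifers 1 to 4, without a dye term, epithelial medians were 2.25, 1.866, 1.502 and 0.553. Cell cycle medians were -0.5, -0.685, -0.158 and -0.148. The cell cycle shift was also lost without heifer 2 (median -0.24) and with array weights (median -0.29).

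Lists of the endocrine programme of the follicle did not pass in the main fit. Of 13 measured genes of the insulin and IGF system, 2 rose, or 4 adjusted over the list alone (median 0.52, camera adjusted p = 0.0828; adjusted p = 0.899 with an estimated correlation). Among other settings, this list passed with a dye term per comparison (camera adjusted p = 0.00307), array weights (0.011), only the arrays of this comparison (0.0106) and without heifer 2 (1.03e-05). Its median was 0.115 without heifer 1 and 0.16 without heifer 3, without passing. IGF2R, the receptor that clears IGF2, rose by 2.81 ± 0.62 and the kinase AKT2 by 1.94 ± 0.34. In the steroidogenesis list 2 of 15 fell, RGN and the cholesterol transporter NPC1 (-1.05 ± 0.31; -0.70 with the covariates, SE 0.32 against 0.21, adjusted p = 0.245), and adjusted over the list alone 3 fell and 1 rose (median -0.51, camera adjusted p = 0.111). HSD3B1, which makes progesterone, stood at -1.74 ± 1.21 (adjusted p = 0.0657). Aromatase, CYP19A1, stood at -0.99 ± 0.62 (adjusted p = 0.275), the FSH receptor FSHR at -1.06 ± 0.44 (adjusted p = 0.121), STAR at 0.64 ± 1.76 and VEGFA at 0.06 ± 0.48. With only the arrays of this comparison CYP19A1 and FSHR passed (adjusted p = 0.0286 and 0.014). They also passed without the 11-month arrays of heifers 1 and 4 (adjusted p = 0.0499 and 0.0288). With the covariates CYP19A1 stood at 0.09, FSHR at -0.01 and STAR at -0.39. Without the 8-month arrays of heifers 1 and 2 these 3 genes stood at 0.01, -0.38 and -0.15. That fit held 8 months in Cy3 only, with a dye term from the 11-month arrays. That fit alone cannot show whether the lower values of CYP19A1 and FSHR remained in heifers 3 and 4. The means and SDs over heifers given above require a lower ratio at 8 months in every heifer for both genes, before any dye correction. They do not show how much lower it was in heifers 3 and 4. Neither probe of the LH receptor gene LHCGR met the filter for signal above background, in any comparison. The granulosa identity list had a median of -0.17 over 21 genes and the ovulatory list one of -0.08 over 15, with 0 members called in either list and 0 adjusted over the list alone. With the covariates these medians were 0.16 and -0.30 and that of steroidogenesis -0.25, without passing, and the insulin and IGF list passed with a lower median of 0.25 (camera adjusted p = 0.00619).

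Single members of further lists changed at 8 months while the lists as groups did not pass. In the stress list JUNB rose by 1.70 ± 0.26 and ATF4 changed by -1.08 ± 0.26, and adjusted over the list alone 4 rose and 1 fell of 26 (median 0.21). Mitochondrial respiration had OGDH risen by 1.47 ± 0.38, with MDH2 at -0.97 ± 0.31 and IDH3A fallen, and adjusted over the list alone 2 rose and 3 fell of 31 (median -0.13). The glycolytic enzyme PFKL rose by 1.65 ± 0.36 in the hypoxia list (median -0.16; 1 rise and 1 fall adjusted over the list alone), and the lysosomal protease CTSD by 1.66 ± 1.08 in the apoptosis list (median 0.26; 2 rises and 1 fall). The interferon regulator IRF7 rose by 1.87 ± 0.45 (list median 0.31), and the matrix protease MMP14 rose 2.83-fold (list median -0.05). VEGFB rose by 0.86 ± 0.52 (list median 0.24), RPS12 by 0.86 ± 0.31 (ribosomal list median 0.20) and THY1 of the theca list by 1.12 ± 0.44 (list median 0.08). Adjusted over the list alone, these lists had 1, 2, 1, 2 and 1 rises. ID2, a BMP target, changed by -1.10 ± 0.36, and 2 rises and 1 fall passed adjusted over the list alone among 25 TGF-beta and BMP genes (median 0.11). SREBF2, a regulator of sterol synthesis, rose by 1.08 ± 0.44 on its brightest probe, but its other probes lay between -1.31 and 0.20, so its direction is unsettled (cholesterol list median 0.13, 1 rise adjusted over the list alone). With the squamous and cilia medians as covariates, CTSD stood at 0.94 (adjusted p = 0.286) and THY1 at 0.46 (adjusted p = 0.39), while JUNB, ATF4, IRF7 and MMP14 still passed. OGDH stood at 1.31, PFKL at 1.38, VEGFB at 1.10, SREBF2 at 1.08, RPS12 at 0.65, ID2 at -0.91, MDH2 at -0.72 and IDH3A at -1.71, changes that grew, held or kept most of their size but had larger SEs and fell short (adjusted p from 0.0672 to 0.259).

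Markers of other cells moved apart between the heifers. Leukocyte markers had a median of -0.37 over 28 genes (camera adjusted p = 0.266), and medians of 0.453, -1.354, 0.175 and -0.245 in heifers 1 to 4. Without heifer 1 their fitted median was -0.765, which passed (camera adjusted p = 4.6e-06), and without heifer 2 it was 0.046. PTPRC stood at -1.66 ± 1.15, CD68 at -1.10 ± 0.75 and S100A9, a calcium-binding protein of neutrophils and keratinocytes, at 3.01 ± 2.82. With the covariates the leukocyte list passed at -0.97 (camera adjusted p = 0.000163), with PTPRC at -2.92 and CD68 at -1.64 called and S100A9 at 0.90, and so did the ribosomal list at 0.53 (camera adjusted p = 0.00629). Medians were -0.15 for endothelial, 0.06 for stromal, -0.30 for oocyte and -0.03 for red blood cell markers and 0.24 for antioxidant genes. Limma called 0 members in these 6 lists, and adjusted over the list alone only the antioxidant list had any, 6 rises and 4 falls of 25. The added list of stratified squamous epithelium had medians of 1.73, 0.08, 0.53 and 0.99 in heifers 1 to 4 at 8 months, and 0 of 10000 random lists were as high as its fitted median of 0.77. Its measured members number 33, of which 4 rose, SFN by 2.12 ± 1.46, S100A14 by 1.42 ± 0.64 and the junction genes CLDN7 by 1.53 ± 0.42 and CDH3 by 1.35 ± 0.49. With the covariates, of which the median of this list is one, none of the 4 passed, with S100A14 at 0.74 and CLDN7 at 0.70, and with SFN at 1.30 and CDH3 at 1.09 (SE 0.39 against 0.25). The added list of motile cilia had medians of 2.38, 3.58, 0.15 and 0.12, with a fitted median of 1.43 that 0 of 10000 random lists reached. DNAH9, an axonemal dynein, stood at 5.81 and 5.55 in heifers 1 and 2 and at 0.23 and 0.60 in heifers 3 and 4, and the oviductal glycoprotein gene OVGP1 at 6.07, 5.13, 0.41 and 0.10.

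**Figure D2:**
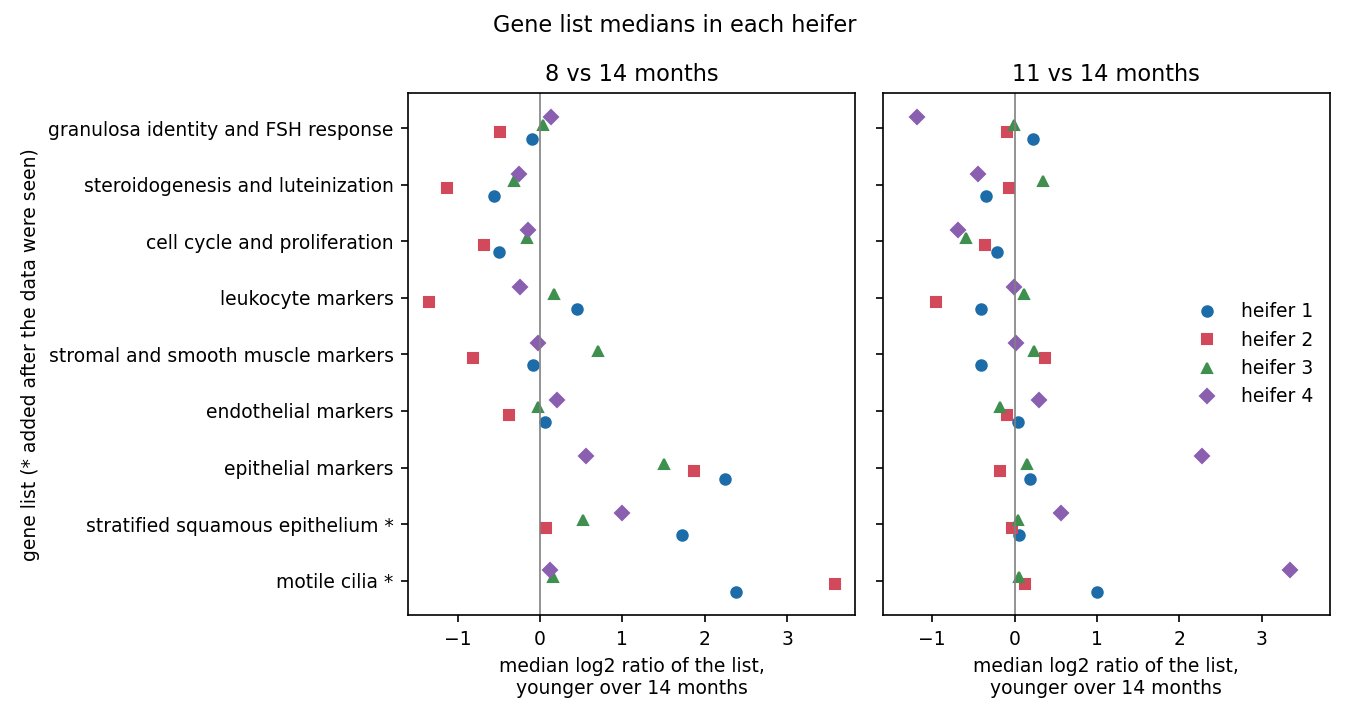
Median log2 ratio of the younger age over 14 months on the horizontal axis for 9 gene lists, with 8 vs 14 months on the left and 11 vs 14 months on the right. Points are the 4 heifers. Motile cilia genes stand at 2.38 and 3.58 in heifers 1 and 2 at 8 months and at 1.01 and 3.35 in heifers 1 and 4 at 11 months.

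At 11 months no single gene passed, and the list with the lowest p was that of the cell cycle. It shifted down from 14 months, with 29 of 31 genes lower and a median of -0.45, negative in each heifer (-0.21, -0.36, -0.60 and -0.69; camera adjusted p = 1.37e-10; adjusted p = 0.0604 with an estimated correlation). The mitotic genes BIRC5, CCNB2, BUB1B and KIF20A stood at -0.86 ± 0.72, -0.84 ± 0.37, -0.82 ± 0.48 and -0.82 ± 0.36. Immediate early and stress genes shifted up with a median of 0.33 over 26 genes (camera adjusted p = 0.00136; adjusted p = 0.697 with an estimated correlation), IER3 at 0.67 ± 0.48 and JUN at 1.10 ± 1.29. Their medians were 0.27, -0.11, -0.02 and 1.05 in heifers 1 to 4, highest in heifers 1 and 4, where motile cilia genes stood highest too, and without the 11-month arrays of these heifers the list no longer passed (median 0.08), nor with the squamous and cilia medians as covariates. The TGF-beta and BMP list shifted up with a median of 0.14 over 25 genes (camera adjusted p = 0.032), with ID1 at 0.83 ± 0.34, ID3 at 0.57 ± 0.64 and SMAD1 at 0.55 ± 0.39. With an estimated correlation its camera adjusted p was 0.0466, but that estimate was 0, below the preset 0.01, so this was not a stricter test. With fry the adjusted p was 0.235. An unadjusted p under 0.05 was found for 2 of the 25 members, against 7.5% of all probes.

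Epithelial markers shifted up at 11 months too, with a median of 0.75 over 12 genes (camera adjusted p = 0.0145; adjusted p = 0.79 with an estimated correlation), but heifer 4 stood at 2.28 against 0.19, -0.18 and 0.16 in heifers 1 to 3, and without heifer 4 the list no longer passed (median 0.14). Nor did it with array weights (0.52), with mean intensities (0.62) or without the 11-month arrays of heifers 1 and 4 (0.02), and with the squamous and cilia medians as covariates its median turned to -0.02. KRT8 stood at 0.83 ± 0.58 and CLDN1 at 0.80 ± 1.14. Leukocyte markers shifted down with a median of -0.27 over 28 genes (camera adjusted p = 0.0444; adjusted p = 0.919 with an estimated correlation), with the T cell gene CD3E at -0.93 ± 0.57 and lysozyme, LYZ, at -1.37 ± 1.49, a shift that passed in 13 of 23 settings. In these 5 lists 0 members passed, also when adjusted over the list alone. Motile cilia genes had medians of 1.01, 0.12, 0.05 and 3.35 in heifers 1 to 4 (fitted 1.16, 0 of 10000 random lists as high), and squamous genes 0.06, -0.03, 0.04 and 0.57 (fitted 0.07, 1783 of 10000 as high).

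Limma called 0 of 22692 probes between 11 and 14 months, with 1702 at an unadjusted p under 0.05 and a lowest adjusted p of 0.661. The smallest p-values among genes with the same direction in 4 heifers belonged to SCAND1 (0.97 ± 0.58), CPEB3 (1.35 ± 0.59), SFPQ (0.86 ± 0.17), CREB3L2 (1.28 ± 0.94) and PHC2 (1.00 ± 0.56) among higher values, and PVRIG (-1.04 ± 0.85), the spindle gene CCDC99, now SPDL1 (-1.10 ± 0.34), the mitotic gene CKAP2 (-0.78 ± 0.23), MTG1 (-0.95 ± 0.67) and LOC512672 (-0.73 ± 0.26) among lower ones. The other probes of SCAND1 gave 0.12 and 0.42. CYP19A1 stood at -0.82 ± 1.58 and FSHR at -0.59 ± 0.99, with heifer 4 at -3.13 and -2.02, STAR at 1.28 ± 1.63 and VEGFA at 0.11 ± 1.31. The list calls depend on single heifers, with 9 lists called without heifer 1 and 3 without heifer 2, and the stress list fell short without heifer 4, the TGF-beta and leukocyte lists without heifer 2 or heifer 3.

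Between 8 and 11 months the ages sat on different arrays, so the contrast cannot be told apart from a difference between the array sets. Epithelial genes were again the higher ones at 8 months. The epithelial list shifted up by a median of 0.77 over 12 genes (camera adjusted p = 0.00194; adjusted p = 0.97 with an estimated correlation), with CLDN4 at 2.56 ± 1.36, KRT7 at 2.35 ± 1.78 and 4 of 12 risen when adjusted over the list alone, although heifer 4 had a median of -1.45 against 2.09, 1.86 and 1.33, and the call was lost without heifer 1 (median 0.39), with the covariates (0.47) and without the 8-month arrays of heifers 1 and 2, where the median turned to -0.20. The last of these fits held 8 months in Cy3 only and took its dye term from the 11-month arrays. Basal keratin KRT5 stood at 2.24 ± 0.49, above background on 1 of 4 arrays at 11 months. Creatine kinase B, CKB, stood at 2.75 ± 0.75, with 0.89 for its other probe, TMEM79 at 2.35 ± 0.98 and ITPKC at 1.36 ± 0.32. MIR2358 was not above background at 11 months and stood about 1.48-fold higher at 8 months, without passing limma's test (adjusted p = 0.727).

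The steroidogenesis list shifted down from 11 to 8 months, with 11 of 15 genes lower and a median of -0.34 (camera adjusted p = 0.0301; adjusted p = 0.97 with an estimated correlation), a shift lost in 7 of 23 settings, without heifer 2 (median -0.08) or heifer 3 (-0.08), without the 8-month arrays of heifers 1 and 2, without background correction, with the strict filter, with mean intensities and with the heifer as a fixed block, where 1 list was called in place of 2. HSD3B1 stood at -1.39 ± 1.58, RGN at -1.13 ± 1.11, SCARB1, the receptor for high-density lipoprotein, at -1.08 ± 1.53 and NPC1 at -0.75 ± 0.64, and 0 members passed adjusted over the list alone. Lower values with the same direction in all heifers belonged to ID2 (-1.28 ± 0.50), TMEM43 (-1.20 ± 0.62), FMO1 (-0.92 ± 0.34), ASF1A (-0.87 ± 0.23) and AMACR (-0.84 ± 0.28). IGF2 stood at -2.17 ± 2.20, CYP19A1 at -0.17 ± 1.71, FSHR at -0.47 ± 1.24, STAR at -0.64 ± 3.27 and VEGFA at -0.06 ± 1.06. Limma called 0 probes here, with 1209 at an unadjusted p under 0.05 and a lowest adjusted p of 0.156, and 19 probes, all higher at 8 months, with a dye term per comparison.

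Over all 3 ages the F test of limma called 223 probes, of which 221 were among those called between 8 and 14 months. This count was 0 without heifer 3 and without heifer 4, 861 without heifer 2 and 2801 without heifer 1. The changes at 8 and at 11 months against 14 months correlated at 0.781 over probes, which are not independent replicates. Both comparisons are against RNA of the same heifers at 14 months, and whether the same extracts were used on both array sets is not given in the sources used here. Simulations with no age effect, in which both arrays of a heifer share its 14-month sample, gave a correlation of 0.501. The covariance was 0.171 against 0.0471 in the simulations, a difference of 0.123. With 8 months taken from 2 heifers and 11 months from the other 2, the correlation lay between 0.37 and 0.553 and the covariance between 0.115 and 0.178.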

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

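The tests of squamous cells, ciliated cells and a lower granulosa share as sources of the epithelial signal, of a single heifer behind the cell cycle shift, and of its dilution at 8 months were chosen only after the result was seen.

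Epithelial genes, with KRT78 and KRT4 in front, were higher at 8 months, while at 11 months the epithelial shift was carried by heifer 4 (2.28), where the cilia median was 3.35 and the squamous median 0.57, and with both medians as covariates it went from 0.75 to -0.02, which leaves open whether it came with such cells or with anything else particular to that array. A lower share of granulosa cells would raise all other cell types alike, but the epithelial median exceeded the leukocyte median at 8 months by a log2 of 1.88 (95% bootstrap interval over genes 1.26 to 2.58). The interval treats genes as independent, although estimated correlations within these lists were 0.658 and 0.438, and it leaves out the spread over heifers. In heifers 1 to 4 epithelial medians were 2.25, 1.866, 1.502 and 0.553. Leukocyte medians were lower in each, at 0.453, -1.354, 0.175 and -0.245. Ciliated cells as the source of the keratin rise are argued against by the cilia median of 0.118 in heifer 4, where KRT4 and KRT78 stood at 4.72 and 5.22. For the keratins at 8 months, a candidate explanation is that cells of a stratified squamous epithelium entered the aspirates. The 27 members of the squamous list whose values had not been seen before had a median of 0.68. The 95th percentile for random lists was 0.177. Genes in those lists were drawn singly, which overstates how rare such a median is, and the squamous list was added after the data were seen. A rise of epithelial genes in general could give the same result, so it does not single out squamous cells. The epithelial list at 8 months no longer passed without the arrays of heifers 1 and 2, where cilia genes stood highest (median 0.42). That fit held 8 months in Cy3 only, with a dye term from the 11-month arrays. It cannot show whether the epithelial shift rests on the arrays left out. At 11 months, by contrast, 1783 of 10000 random lists were as high as the squamous list. Of the 33 measured members, 24 were above background at 14 months and 0 belong to another list. MAL (2.99 ± 1.73), KRT14 (2.44 ± 2.34) and IVL (1.92 ± 1.61) stood high without passing limma's test (adjusted p = 0.0507, 0.0902 and 0.0678). TP63 (-0.18 ± 0.28) and TGM3 (-1.34 ± 2.11) did not stand high, which the candidate explanation leaves unexplained. The labels name no sort that would remove squamous cells, and an effect of age on the granulosa cells stays open and untested.

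More probes rose (735) than fell (136) at 8 months, but this split depends on the fit, with 2276 higher and 2003 lower at an unadjusted p and a change of at least 1.5-fold, and with 495 higher and 998 lower when the squamous and cilia medians are covariates. In that fit the probes called as risen without it kept a median log2 of 1.199 (95% bootstrap interval over probes 1.16 to 1.24), against 1.25 before, and 260 of 735 were still called, with a median SE of 0.321 against 0.22 and 3 residual degrees of freedom against 5. This median stayed above the bound set in advance. The probes were chosen from these same values for a small p, which favours changes alike in all heifers, while the covariates differed between heifers. Such probes tend to lose little to them, so the fit does not decide whether the epithelial signal that the covariates follow is the source. The same covariates took the epithelial list from a median of 1.51 to 0.44 and KRT7 from 2.69 to 0.70. Epithelial signal that they do not follow stays open, because KRT4 was left at 2.43 of 4.29 and KRT78 at 2.60 of 4.34, as does age, which was not tested apart. Signal particular to single probes stays open as well. For 147 risen genes the probe with the smallest p had a median of 1.23. Their other kept probes, called ones included, had a median of 0.336 (95% bootstrap interval 0.234 to 0.418), with 113 genes higher and 34 lower. Choosing the smallest p favours a larger change, so part of this gap arises without such signal, and the values do not decide.

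The cell cycle list lay lower at 8 and at 11 months than at 14 months at the preset correlation, with 0 of 31 members called in either comparison and adjusted p = 0.899 and 0.0604 with an estimated correlation. The 14-month sample of 1 heifer is argued against, because the median without any 1 heifer was at most -0.242 in either comparison. Dilution by epithelial cells is argued against at 11 months, where the median with both covariates was -0.301 (95% bootstrap interval over genes -0.369 to -0.229), and where heifers 2 and 3, with epithelial medians of -0.18 and 0.16, had cell cycle medians of -0.36 and -0.60. At 8 months the median with covariates was -0.086 (interval -0.31 to 0.078), so dilution stays open there. Both intervals treat genes as independent, although the estimated correlation within the list was 0.231, and they leave out the spread over heifers. An effect of age and a difference between sampling sessions were not tested.

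Single heifers stood far from the others in 10 of 142 values tested, where chance gives about 7.1. At 8 months heifer 1 stood apart for PI3 (6.18), KRT7 (4.14), PFKL (2.18) and BIRC5 (-0.62), and heifer 2 for IGF2R (1.88), CDH3 (0.62) and for the insulin and IGF list (median -0.11). At 11 months heifer 4 stood apart for the epithelial list (2.28), the squamous list (0.57) and KDR (4.18). By the tests of the difference between 8 and 11 months, the epithelial list differed with a camera adjusted p of 0.00194 and the steroidogenesis list with 0.0301, with 0 members called in either. The ages lay on separate array sets, and with an estimated correlation the adjusted p was 0.97 for both lists. Control spots that enter no comparison gave signal, with lowest medians per array and channel of 8533.5 for E1A and 5442.5 for DCP, against at most 349.5 for the threshold from negative controls.

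The signs of the 4 heifers' ratios can be turned in 7 patterns, or 8 for 8 against 11 months, the real one included, which is too few for a share under 0.05. Between 8 and 14 months the real pattern gave 871 probes and the highest other 0, so 1 of 7 patterns was as large, and the F test gave 223 against 0, again 1 of 7. When the 8- and 11-month arrays were exchanged instead, 1382 probes were called between 8 and 14 months with those of heifer 2 and 1063 with those of heifer 4, more than the real 871, and 1345 between 11 and 14 months with those of heifers 3 and 4, against the real 0, while the F test gave at most 97. Between 11 and 14 months 0 probes were called by the real and by every other pattern, 7 of 7 as large, and between 8 and 11 months 0 in 8 of 8. For gene lists the real counts were 2, 5 and 2, and the highest others 9, 8 and 13, with 7 of 7, 4 of 7 and 8 of 8 patterns as large. Some patterns and exchanges called more lists than the real one, and some exchanges more probes. Whether a structure of the samples lies behind this was not tested.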

How the results depend on the processing

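Covariates, mean intensities, plain background subtraction, kept marked spots and the fits without 2 of the 8 arrays, 6 of 28 settings, were chosen after seeing the data. Between 8 and 14 months the 871 probes became 1708 with median normalization, 2020 with a dye term per comparison, 3553 with array weights, 3236 with only its own arrays, 4279 at unadjusted p with a 1.5-fold change, 456 as gene means (fewer items tested) and 1493 with covariates, and 0 to 1705 without 1 heifer. All 871 kept their direction with the covariates and 286 were called in both fits. The 0 calls between 11 and 14 months became 1024 unadjusted. Those between 8 and 11 months became 19 with a dye term per comparison, 1 with array weights and 1049 unadjusted, and stayed 0 with the heifer as a fixed block. The 223 probes of the F test became 425 with median normalization, 52 without the dye term, 436 without the heifer block, 1897 with array weights, 139 with 1 probe per gene, 45 as gene means, 402 with mean intensities, 42 without the 8-month arrays of heifers 1 and 2, 111 without the 11-month arrays of heifers 1 and 4, 23 with covariates and 0 to 2801 without 1 heifer. Without the block the leukocyte list at 11 months also fell short, and with the fixed block the steroidogenesis list. List counts of 2, 5 and 2 became 0, 1 and 0 with the estimated correlation and 0, 0 and 0 with fry. The 1 list left was that of TGF-beta and BMP genes, whose estimate of 0 lay below the preset. The 5 lists at 11 months became 1 with array weights and 3 with mean intensities, the 2 at 8 months 5 without the 11-month arrays of heifers 1 and 4, and the 2 of 8 against 11 months 1 without background correction, with the strict filter or with the fixed block and 5 with covariates. Without 1 heifer they ranged from 2 to 4, 3 to 9 and 1 to 6. The cell cycle shift at 11 months passed in 23 of 23 settings with medians from -0.58 to -0.30. That at 8 months passed in 19 of 23 with medians from -0.46 to -0.04. Neither passed with the estimated correlation (camera adjusted p = 0.0604 and 0.899) or with fry (adjusted p = 0.235 and 0.352). Scaling of brightness between arrays is among the 23 settings and leaves the log2 ratios as they are, so it could lose no call. Of the other shifts at 11 months, that of TGF-beta genes passed in 20 of 23 settings, of stress genes in 19, of epithelial markers in 18, with a median that turned to -0.02 with covariates, and of leukocyte markers in 13, lost without background correction, without the block, without heifer 2 or 3, without the 11-month arrays of heifers 1 and 4 and with median normalization, the strict filter, array weights, mean intensities or plain subtraction. The epithelial shift at 8 months passed in 21 of 23, that of 8 against 11 months in 20, turned to -0.20 without the 8-month arrays of heifers 1 and 2, and the steroidogenesis shift in 16. The correlation of 0.781 became 0.55 without the 11-month arrays of heifers 1 and 4 and ranged from 0.594 to 0.789 without 1 heifer. SREBF2 turned to -0.041 as the mean of its probes, because they disagree. Of 43 called genes named for 8 months, 43 lost the call without heifer 3, 40 without heifer 4, 23 with covariates and 23 with mean intensities, while all 43 kept their sign without any 1 heifer. Apart from these reasons the cause was not tested. Only the arrays of the comparison could not be applied to 8 against 11 months. The filter on dim probes moved the 871 to 800 when left out and to 925 when strict, and probes below background support no statement.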

Other observations

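The cilia and squamous lists were added after the data were seen. Values of 6 of 33 measured squamous members and of 0 of 24 cilia members had been seen by then. The single genes here were chosen after their values were seen. Among the 8-month arrays, heifer 2 had the highest cilia median (3.58) and the lowest squamous median (0.08), while heifer 4 at 8 months had 0.12 and 0.99. KDR, the VEGF receptor of endothelium, stood at 1.54, 3.62, 0.63 and -0.40 in heifers 1 to 4 at 8 months and at 0.32, 0.73, 0.29 and 4.18 at 11 months, highest in the samples with the highest cilia medians, while the endothelial list as a whole had a median of -0.38 in heifer 2 at 8 months and 0.29 in heifer 4 at 11 months. In heifer 4 at 11 months, where the cilia median was 3.35, the granulosa identity list had a median of -1.19, the lowest of all 8 arrays.

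S100A9 belongs to the leukocyte list but had high values where KRT4 had them. It stood at 5.30, -1.10, 3.68 and 4.17 in heifers 1 to 4 at 8 months, with KRT4 at 6.07, 1.47, 4.89 and 4.72 and PTPRC at -0.45, -0.97, -2.96 and -2.25. STAR had no common direction, with 3.19, -0.80, -0.05 and 0.20 at 8 months and -0.62, 2.73, 2.52 and 0.46 at 11 months.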
